A study of Mus musculus with 6 samples.

How the data were processed

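Per the labels' protocols, RNA was extracted from sorted hematopoietic stem cells with Trizol, turned into amplified cDNA with the SMART-Seq v4 kit and made into libraries with the Nextera XT kit, neither of which marks the strand of a transcript. Per the submitters' processing notes, reads were aligned with STAR and counted per gene with featureCounts on genome build mm10, and the versions and the gene annotation are not given in the sources used here. The authors deposited 1 table with 24110 genes by symbol, a gene length, and 1 column for each of 6 libraries. Per the file headers the last line holds each library's total. The deposited column of Prmt5 fl/fl replicate 2 holds whole-number read counts. The deposited columns of the other 5 libraries hold a scaled signal: each gene's count was multiplied by the total of Prmt5 fl/fl replicate 2 (44704636) and divided by the library's own total. Undoing this factor gave whole reads for 100% of the values in each library, within a tolerance of 1e-06, so depth was known. The deposited gene length, a property of the gene and not a measurement, was used only to look for length trends. All 6 columns were matched to samples by title, and 6234 genes were at 0 in all libraries.

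The 6 libraries formed 2 groups of 3 from the genotype in the labels. Each library was a separate sample with cells from 2 mice, so p-values reflect the spread between pools of animals. The groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Values were taken as log2(value + 1), genes with a mean of at least 10 scaled counts over all libraries were kept (14113), and the genotypes were compared with limma's moderated test with a mean-variance trend, two-sided, with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used, with Python 3.11.15 and matplotlib 3.10.9 for the plots. Total counts of 37834096 to 44704636 put the counting error of a gene at 1000 reads far below the spread between libraries, and that spread limits the precision.

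The replicate numbers in the labels go with title prefixes shared by 1 fl/fl and 1 KO library each, and the mice were matched by litter, so the numbers were taken to pair the libraries, although the labels do not say what the prefix means. The correlations across genes of the deviations from the group means were -0.14, 0.067 and -0.26 for the 3 same-number pairs. The fit with the replicate number as a block has 2 residual degrees of freedom and is given beside each named gene past the threshold over all genes, and each of the 27 lists, whose call it changed. Pairs of libraries differed by a chi-square per degree of freedom of 26.2 to 357, so no library was a copy of another. Correlations between log2 values within a group averaged 0.955 to 0.972 per library.

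The named genes were Prmt5, Trp53 and the genes of the sorting gate; the 10 with the largest log2 fold change in each direction among genes past the threshold with the groups apart and a mean log2 value above the median of all tested genes, leaving out clone-like symbols; in each list with a gene past the threshold the up to 4 members with the smallest p, in each other list the 1 with the smallest; and the PRMT family. Of 14 higher and 22 lower candidates the rule took 10 each, and 73 genes were named in all. Some genes that the rule took are not reported here. Genes outside the rule that are named in the text were chosen after their values were seen. Coordinates came from GENCODE M21 on GRCm38/mm10 by symbol, leaving out symbols that it gives to several genes, and 13452 of the tested genes (95.3%) were matched. The symbols Fam132a, Prmt10 and Ddit3 were not matched.

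The 27 gene lists covered p53 targets, DNA repair (2 lists), the PRMT family, splicing factors (2 lists), the integrated and endoplasmic reticulum stress responses, ribosomal proteins, translation factors, PI3K, AKT and mTOR signaling, tRNA synthetases, proteasome, oxidative phosphorylation, stem cell genes, cell cycle (2 lists), interferon-stimulated genes, the BCL2 family, and markers of 8 other cell types. No gene was in more than 1 list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists. With an estimated correlation and all libraries camera called 0 lists. That version rests on the 4 residual degrees of freedom, and on fewer with a library left out. A missing call there is therefore weak evidence that a list did not change. Fry, which tests whether the genes of a list move one way without comparing them with other genes, called 0 after adjustment. Fry's mixed test, which asks whether genes of a list change in either direction, called 4: the p53 targets (adjusted p = 0.00594), the PRMT family, which holds Prmt5 (3.64e-05), the stem cell genes (0.0136) and the megakaryocyte and platelet markers (0.00594).

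The fit was tested on simulated counts drawn for the 14113 genes with the means and depths of these libraries. It called 51 of 100 genes changed 2-fold and 100 of 100 changed 4-fold in the right direction, 15 of 13718 unchanged genes, and 1 of 26 lists with no change. With the block it called 35 and 100 of the changed genes. The changed genes came from those above the median expression and outside the lists. Libraries of a genotype shared the same simulated means, so the shifts of single libraries seen in the real data were absent. The counts may therefore overstate what the fit and the block detect in the real data, where the block called Gem alone. The 15 false calls are also a larger share of all calls than of the 13718 unchanged genes. The simulated genes were drawn independently of each other. In the real lists the estimated correlation ran from -0.0312 (B cell markers) to 0.902 (ribosomal proteins). The simulation therefore cannot show how often camera calls an unchanged list of correlated genes. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter 10 times as strict, a common total, median-of-ratios size factors, quantile normalization, the block, limma without the trend, robust limma with array weights, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, other thresholds, and leaving out each library. After the data were seen, a fit without both libraries numbered 3 was added, as was camera's estimated correlation together with leaving out each library. Another added fit removed from each library a joint trend on gene length and mean expression. It is called the length trend below, although it did not isolate gene length. The table held no mitochondrially encoded genes, and no exon or junction values were used here, so splicing was not analysed.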

Results

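RNA was sequenced from hematopoietic stem cells, the bone marrow cells that renew all blood lineages, sorted from mice as Lineage-negative, Sca-1-positive, CD48-negative and CD150-positive cells. The animals carried either an intact floxed Prmt5 gene (Prmt5 fl/fl) or the deleted form (Prmt5 KO), were C57BL/6, and were sampled 7 days after the deletion was induced. Each group held 3 libraries, and the cells of each library came from 2 pooled mice, matched between genotypes for litter and sex. Prmt5 encodes an arginine methyltransferase whose substrates include Sm proteins of the spliceosome, and the series title links the enzyme to splicing in these cells. The deposited values are totals per gene, so transcript levels could be compared and the use of exons or introns was not analysed here. The libraries held 44166334, 44704636 and 42213314 reads in genes for Prmt5 fl/fl replicates 1 to 3, and 37834096, 41812565 and 37844477 for Prmt5 KO replicates 1 to 3. The totals did not overlap between the genotypes (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries can give), and all values below are scaled to 1 common total of 44704636. Xist, made from the inactive X chromosome of female cells, was at 1689 to 4550 scaled counts across the libraries, and the Y-linked gene Ddx3y at 1434 to 2903, so both were present in every pool.

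The targeted gene was measured first. Prmt5 (chromosome 14, 54507187 to 54517525, minus strand, 17 exons, GRCm38/mm10 with GENCODE M21) was at 6076, 6024 and 6010 scaled counts in Prmt5 fl/fl replicates 1 to 3. It was at 1056, 1049 and 897 in Prmt5 KO replicates 1 to 3. The means were 6037 ± 34.9 and 1001 ± 90.2 (SD, n = 3 each), a log2 fold change of -2.60 with a standard error of 0.13 (limma, adjusted p = 6.18e-04), so every library matched its label. With the replicate number as a block the fold was the same and the limma adjusted p was 0.0618. The deleted part of the gene is not given in the sources used here, and reads from the remaining exons count toward these values.

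Genes past the limma threshold in Prmt5 KO included 7 of 30 targets of the transcription factor p53, all higher, and 2 of 14 megakaryocyte and platelet markers and 1 of 10 red cell precursor markers, all lower. As lists these 3 were called by camera with a preset correlation and not with an estimated one (adjusted p = 0.770, 0.949 and 0.949). Gem, a small GTP-binding protein of the RGK family, rose from 788 ± 120 to 18601 ± 5284 scaled counts (SD, n = 3 each), a log2 fold change of 4.54. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 699 ± 165 to 5002 ± 1632, a log2 fold change of 2.81. Itga2b, the integrin subunit CD41 of megakaryocytes and platelets, fell from 24378 ± 5203 to 6305 ± 1202, a log2 fold change of -1.95. Mfsd2b, a sphingosine-1-phosphate exporter of red cells and platelets, fell from 7892 ± 1164 to 1464 ± 138, a log2 fold change of -2.42. The limma adjusted p was 6.18e-04 for Gem, 0.0195 for Cdkn1a, 0.0195 for Itga2b and 0.00264 for Mfsd2b. With the replicate block it was 0.0219 for Gem, 0.19 for Cdkn1a, 0.103 for Itga2b and 0.102 for Mfsd2b.

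Of 14113 genes tested, 39 were higher and 64 lower in Prmt5 KO (limma, adjusted p at most 0.0496), 35 and 52 of them by more than 2-fold. All 103 had the 3 KO values on one side of the 3 fl/fl values. A single direction within each of the 3 pairs of libraries that share a title prefix was bound to follow from this. Over all genes tested, 3974 (28.2%) had the groups apart in this way, against 10% by chance, and 2571 had an unadjusted p below 0.05, against 706 by chance. Counts of list members at an unadjusted p below 0.05 given below are to be read against those 2571 of 14113 genes. The share of higher genes among the calls was 37.9%. It was 61.4% with median-of-ratios size factors (35 higher and 22 lower), 59.4% with quantile normalization (38 and 26) and 56.7% with edgeR on the recovered reads (34 and 26), while DESeq2, which also uses size factors, gave 37.2% (365 and 616). On the main scaling it was 57.1%, 66.7% and 78.9% without fl/fl replicate 1, fl/fl replicate 2 and KO replicate 2. With the replicate block, limma called 1 gene higher, Gem (adjusted p = 0.0219), and 0 lower, with 1981 genes at an unadjusted p below 0.05. Each library moved these counts by more than 1.5 times. Without Prmt5 fl/fl replicate 1 the calls were 4 higher and 3 lower, without fl/fl replicate 2 they were 4 and 2, and without fl/fl replicate 3 they were 121 and 257. Without KO replicates 1, 2 and 3 in turn they were 1 and 2, 15 and 4, and 1 and 2.

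**Figure D1:**
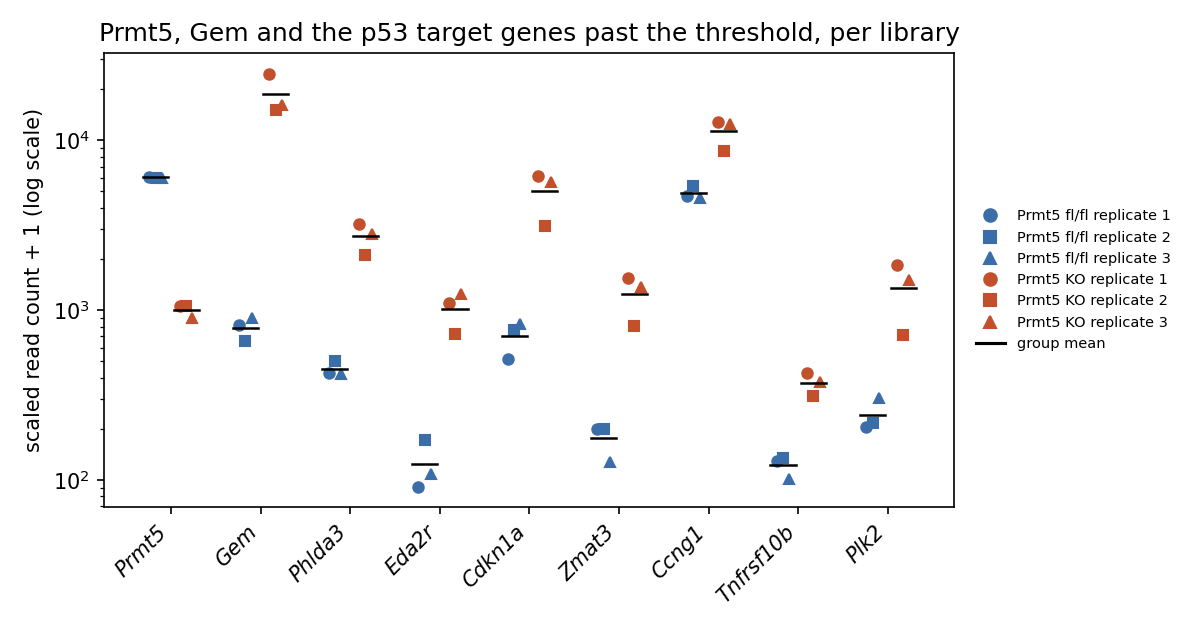
Scaled read count plus 1 (log axis) in each library of Prmt5, of Gem, which is not in the p53 list, and of the 7 of 30 p53 target genes past the limma threshold. Prmt5 fl/fl is in blue and Prmt5 KO in red-orange, with 1 symbol shape per replicate number and a black line at each group mean. Prmt5 lies between 6010 and 6076 in fl/fl and between 897 and 1056 in KO, while Cdkn1a lies between 511 and 822 in fl/fl and between 3140 and 6182 in KO.

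Besides Gem and Cdkn1a, 8 further genes were named by a fixed rule among the higher ones, with log2 fold changes from 1.09 to 1.57. Slc19a2, a thiamine transporter, rose from 1025 ± 131 to 3032 ± 333, and Gtse1, a protein of the G2 and S phases that binds p53, rose from 2263 ± 56.8 to 6244 ± 1004. Egr1, an immediate early transcription factor, rose from 2328 ± 210 to 6057 ± 1063, a log2 fold change of 1.37 (limma, adjusted p = 0.0301). Ercc5, the XPG endonuclease of nucleotide excision repair, had a log2 fold change of 1.25, and Ccng1, cyclin G1, one of 1.19. The values for Gch1, the first enzyme of tetrahydrobiopterin synthesis, and Gja1, connexin 43, were 1.12 and 1.09. The mitotic kinase Nek6 rose by a log2 of 1.23, but its locus overlaps Psmb7 on the other strand, and the library kit does not mark strand. With the replicate block the limma adjusted p of these 8 genes was 0.19 for Slc19a2 and Gtse1 and 0.197 for the others. Their calls were lost without each library in turn other than fl/fl replicate 3, except those of Gtse1, Egr1 and Ccng1 without KO replicate 2. Gem lies on chromosome 4 (11704457 to 11714752), Cdkn1a on chromosome 17 (29090976 to 29100727) and Egr1 on chromosome 18 (34859823 to 34864984).

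Among the lower genes, Csad, an enzyme of taurine synthesis, fell from 2678 ± 87.0 to 872 ± 250, a log2 fold change of -1.66. Ache, acetylcholinesterase, fell from 2300 ± 239 to 828 ± 91.5 (log2 -1.47), and Art4, the carrier of the Dombrock blood group, fell from 3182 ± 437 to 1224 ± 197 (log2 -1.38). Fam132a had a log2 fold change of -1.31 and Slc18a2, the vesicular monoamine transporter, one of -1.20. Fam173a (log2 -1.37) and Haghl (log2 -1.19), both on chromosome 17, fell as well. Reads of Fam173a cannot be told apart from those of the overlapping Ccdc78 and AC134908.4, nor those of Haghl from Narfl, nor those of Slc18a2 from Gm29261. Without each library in turn other than fl/fl replicate 3 these 7 calls were lost, except that of Csad without KO replicate 2. Those of Fam173a and Haghl were lost in 11 of 20 alternatives, among them edgeR (adjusted p = 0.0634 and 0.0573) and median-of-ratios size factors (limma adjusted p = 0.0664 and 0.0626). Itga2b lies on chromosome 11 (102453297 to 102470122, 30 exons) and Mfsd2b on chromosome 12 (4862440 to 4874359). Of the 25 named genes past the threshold, Gem alone stayed past it with the replicate block, and the blocked limma adjusted p of the others ran from 0.0618 to 0.197.

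The p53 target genes, a list of 30 fixed beforehand, stood out among the groups tested. Of its members 7 rose: Cdkn1a, Ccng1, Phlda3, Eda2r, Zmat3, Tnfrsf10b and Plk2. Phlda3, a repressor of AKT, rose from 447 ± 44.9 to 2712 ± 561 (log2 2.58; limma adjusted p = 0.00564). Eda2r, a receptor of the tumor necrosis factor receptor family, rose from 122 ± 42.1 to 1017 ± 270 (log2 3.06), and Zmat3, an RNA-binding zinc finger protein, from 174 ± 41.1 to 1241 ± 393 (log2 2.80). Tnfrsf10b, the TRAIL receptor, and Plk2, a polo-like kinase, had log2 fold changes of 1.60 and 2.40. Adjusted over the list alone, 20 members were higher and 0 lower, edgeR called 6 higher and 0 lower, DESeq2 called 21 and 0, and 28 of the 30 folds were above 0. The median log2 fold change of the list was 1.08 (camera with a preset correlation, adjusted p = 6.51e-20), and the medians within the 3 same-prefix pairs were 1.26, 0.665 and 1.83. With an estimated correlation the camera adjusted p was 0.770 (0.0285 before adjustment), and fry gave an adjusted p of 0.0878 (0.00325 before adjustment). Mdm2, the ubiquitin ligase of p53, had a log2 fold change of 0.50 (limma, adjusted p = 0.180) and Bax, an activator of cell death, one of 1.06 (limma, adjusted p = 0.0676). Trp53 itself was at 14941 ± 1059 and 17173 ± 1909 (log2 0.20; limma adjusted p = 0.450). The limma adjusted p of the 7 members ran from 0.143 to 0.197 with the replicate block, so none of them stayed past the threshold, and 19 members had an unadjusted p below 0.05. Without Prmt5 fl/fl replicates 1, 2 and 3 in turn 1, 2 and 13 members were past it, and without KO replicate 2 there were 6. Without KO replicate 1 or KO replicate 3 limma called 0, with 17 members at an unadjusted p below 0.05 each time.

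Genes of DNA repair did not move as a group. Of 36 genes for interstrand crosslink repair and homologous recombination, 0 passed the limma threshold over all genes and 0 adjusted over the list alone. Of these, 10 had an unadjusted p below 0.05, all lower, and edgeR and DESeq2 called 0 and 3. Their median log2 fold change was -0.10 (camera, adjusted p = 0.188), with Fance, a subunit of the Fanconi anemia core complex, at -0.60 (limma, adjusted p = 0.0989). Without Prmt5 fl/fl replicate 3 the list was lower (camera, adjusted p = 0.00858; with an estimated correlation adjusted p = 0.907). Of 39 genes of other DNA repair pathways, 1 rose, Ercc5, and 0 fell, with the same counts adjusted over the list alone and by edgeR, while DESeq2 called 1 higher and 1 lower (camera, adjusted p = 0.927). The limma adjusted p of Ercc5 was 0.197 with the replicate block, and 0.0873 to 0.228 without each library in turn other than fl/fl replicate 3. The list's median of -0.016 and mean of -0.0060 were below 0 while camera's direction was up. Neil3, a DNA glycosylase, had a log2 fold change of -0.97 (limma, adjusted p = 0.0894).

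In the list of 12 arginine methyltransferases and PRMT5 partners, Prmt5 was the single gene past the threshold (camera, adjusted p = 0.567; 0.0255 on DESeq2's statistics). Adjusted over the list alone, 1 was higher and 3 lower: Prmt1, the main enzyme of asymmetric arginine dimethylation, at 9785 ± 289 and 12672 ± 945 (log2 0.37), Prmt5, Prmt2 (log2 -0.63) and Prmt10 (log2 -0.49). The list's median was 0.0076 and its mean -0.28, the mean and camera's direction both down. Wdr77, which forms the methylosome with PRMT5, was at 9684 ± 289 and 9818 ± 980 (log2 0.015; limma adjusted p = 0.957), a direction that turned with quantile normalization. Riok1, an adaptor of PRMT5, was at 3638 ± 254 and 3633 ± 115.

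Both lists of splicing factor genes were called higher by camera with a preset correlation and neither with an estimated one or by fry (adjusted p = 0.17 and 0.95). The list of 44 SR, hnRNP and U2-associated genes had 34 folds above 0 and a median log2 fold change of 0.16 (camera, adjusted p = 1.39e-04; with an estimated correlation adjusted p = 0.949). Limma called 0 of them over all genes and 0 adjusted over the list alone, 7 had an unadjusted p below 0.05, all higher, and edgeR and DESeq2 called 0 and 3. Sf3b1, a subunit of the U2 snRNP, was at 24752 ± 1469 and 31146 ± 891 (log2 0.33; limma adjusted p = 0.157). The medians within the same-prefix pairs were 0.189, 0.194 and -0.014. The list of 31 Sm, LSm and snRNP assembly genes had a median of 0.12 (camera, adjusted p = 0.0396; with an estimated correlation adjusted p = 0.978; with the replicate block adjusted p = 0.0504). None of the 31 passed the limma threshold, over all genes or adjusted over the list alone, 2 had an unadjusted p below 0.05, and edgeR and DESeq2 called 0. Its pair medians were 0.248, 0.215 and -0.257. The camera adjusted p was 0.246 without fl/fl replicate 1, 0.659 without fl/fl replicate 2, 0.335 without KO replicate 1 and 0.0907 without KO replicate 2. It was 1.02e-05 without fl/fl replicate 3 and 0.000632 without KO replicate 3, and with an estimated correlation 0.907 and 0.874.

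**Figure D2:**
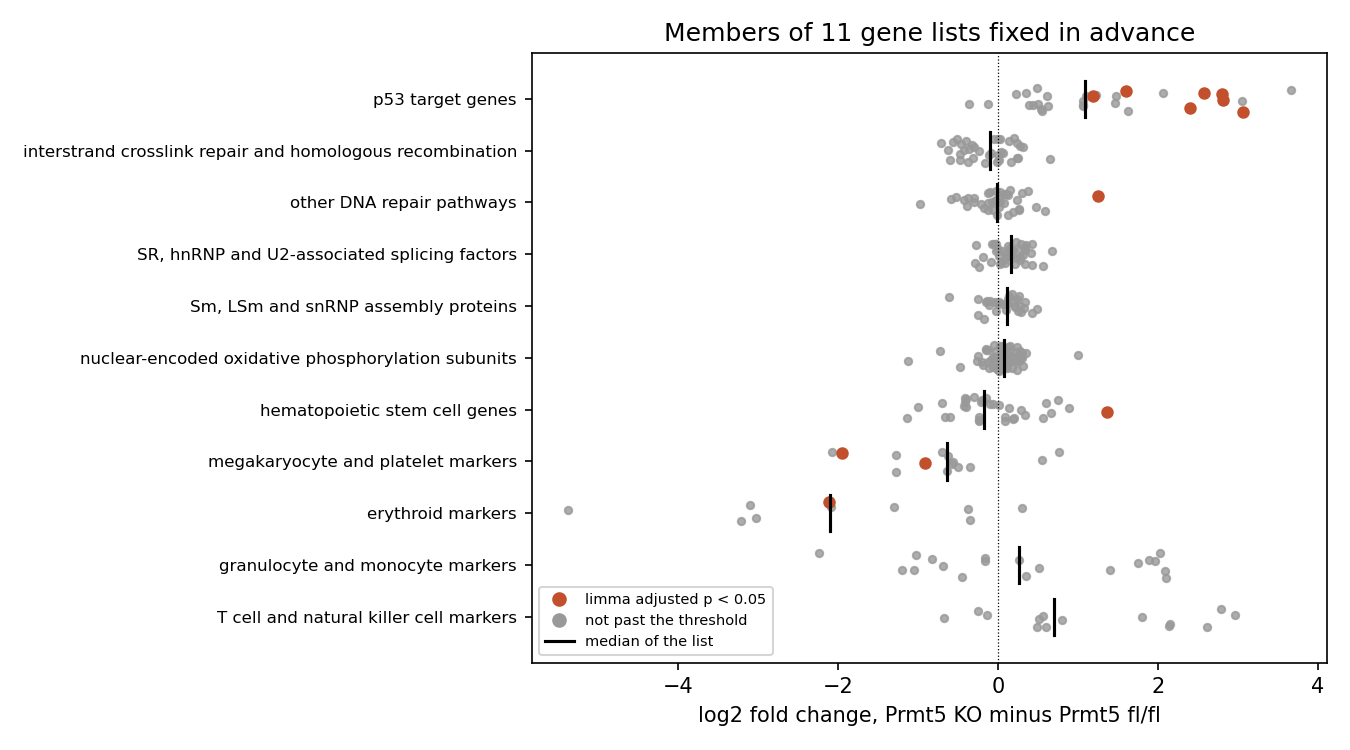
Log2 fold change of Prmt5 KO over Prmt5 fl/fl (horizontal axis) for the tested members of gene lists (vertical axis), with genes past the limma threshold in orange, others in grey and a black bar at each list's median. The p53 target list has a median of 1.08 with 28 of 30 genes above 0, and the erythroid list a median of -2.10 with 9 of 10 below 0.

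Markers of megakaryocytes and platelets were called lower as a list by camera with a preset correlation, but not with an estimated one or by fry (adjusted p = 0.17). Of 14 members, 2 fell: Itga2b and Rab27b, a GTPase of granule release, which went from 3955 ± 297 to 2103 ± 251 (log2 -0.91; limma adjusted p = 0.0475). With the replicate block their limma adjusted p was 0.103 and 0.197. Without each library in turn other than fl/fl replicate 3 neither gene was past the threshold, with a limma adjusted p of 0.0627 to 0.142 for Itga2b and 0.104 to 0.194 for Rab27b. Without fl/fl replicate 3 limma called 5 members lower. EdgeR called 1 member lower, without Rab27b (adjusted p = 0.0653), and DESeq2 called 5. Adjusted over the list alone 6 were lower and 0 higher, and 12 of 14 folds were below 0. The median log2 fold change was -0.63 (camera, adjusted p = 3.23e-04; with an estimated correlation adjusted p = 0.949), and the pair medians were -0.29, -1.11 and -1.21. The platelet receptor subunit Gp5 was at 5643 ± 1402 and 2317 ± 457 (log2 -1.27) and Treml1, a receptor of platelet granules, at 1396 ± 573 and 330 ± 141 (log2 -2.08), both with a limma adjusted p of 0.0637. The platelet chemokines Pf4 (log2 -0.63) and Ppbp (log2 0.77) did not pass the test (limma, adjusted p = 0.460 and 0.663). In Prmt5 fl/fl replicate 3 the members stood at a median log2 of 0.58 above the other fl/fl libraries, and without that library the list kept its camera call (adjusted p = 3.60e-04; with an estimated correlation adjusted p = 0.907).

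Markers of red cell precursors were called lower as a list by camera with a preset correlation and not with an estimated one, and their values spread widely between libraries. Of 10 tested members 1 fell, Klf1, a transcription factor of erythroid genes, from 1446 ± 612 to 319 ± 70.4 (log2 -2.11; limma adjusted p = 0.0476), and the count adjusted over the list alone was also 1. Its limma adjusted p was 0.161 with the replicate block, and 0.0773 to 0.22 without each library in turn other than fl/fl replicate 3. EdgeR called 0 members, with Klf1 at an adjusted p of 0.0653, DESeq2 called 2 lower, and 4 had an unadjusted p below 0.05 by limma, all lower. The median log2 fold change was -2.10 and 9 of 10 folds were below 0 (camera, adjusted p = 0.00468; with an estimated correlation adjusted p = 0.949). Slc4a1, the band 3 anion exchanger, was at 1395, 218 and 86.8 in fl/fl replicates 1 to 3 and at 2.36, 0 and 110 in KO replicates 1 to 3. Rhd, the Rh blood group antigen, was at 1120, 126 and 248 in fl/fl and at 55.5, 8.55 and 81.5 in KO. The pair medians were -3.20, -2.21 and -0.546, and without Prmt5 fl/fl replicate 1 the camera adjusted p was 0.0692. Without fl/fl replicate 3 it was 0.00413, and 0.907 as the adjusted p with an estimated correlation. The hemoglobin genes Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2 are listed at 0 in all libraries, as is Rpl26, a ribosomal protein gene, so they give no measure of red cell content.

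**Figure D3:**
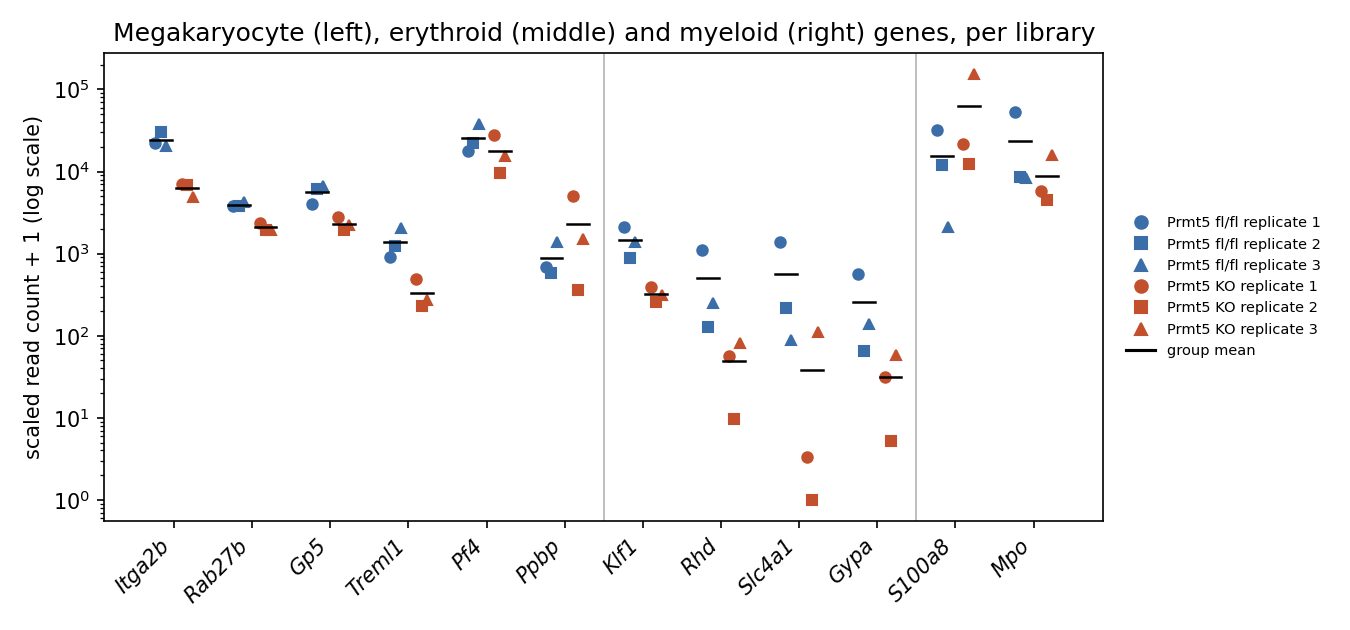
Scaled read count plus 1 (log axis) of megakaryocyte (left), erythroid (middle) and myeloid (right) genes in each library, with Prmt5 fl/fl in blue, Prmt5 KO in red-orange, 1 symbol shape per replicate number and a black line at each group mean. Itga2b lies between 20679 and 30328 in fl/fl and between 4926 and 7124 in KO, while Slc4a1 overlaps between the groups, from 86.8 to 1395 in fl/fl and from 0 to 110 in KO.

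Genes of the stem cell state went both ways. Of 34 members, 1 rose, Egr1, and 0 fell, while adjusted over the list alone 2 were higher and 4 lower (camera, adjusted p = 0.788, median log2 -0.17). EdgeR called 1 higher and 0 lower, and DESeq2 called 3 and 4. With the replicate block the limma adjusted p of Egr1 was 0.197, and without fl/fl replicates 1 and 2 and KO replicates 1 and 3 in turn it was 0.0819, 0.121, 0.187 and 0.184. Procr, the endothelial protein C receptor, was the other higher one (log2 0.60), and the lower ones included Pdzk1ip1, at 8362 ± 3571 and 3600 ± 427 (log2 -1.14; limma adjusted p = 0.105), and Txnip (log2 -0.70; limma adjusted p = 0.120). The genes of the sorting gate did not pass the test: Ly6a, which encodes Sca-1, had a log2 fold change of 0.28 (limma, adjusted p = 0.595), Slamf1, which encodes CD150, -0.24 (0.517) and Cd48 -0.10 (0.857). Kit had 0.09 (0.911), and without Prmt5 fl/fl replicate 3 its value was -0.36.

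Of 6 lists of markers of other blood and stromal cells, 1 was called. T cell and natural killer cell genes were higher (14 members, 0 past the limma threshold, 1 at an unadjusted p below 0.05, 0 adjusted over the list alone, 0 by edgeR and 2 by DESeq2, median log2 0.70; camera adjusted p = 0.0328). With an estimated correlation the adjusted p was 0.978, the pair medians were 0.288, -0.118 and 3.26, and without Prmt5 KO replicate 3 the camera adjusted p was 0.578. It was 0.0996 and 0.0922 without fl/fl replicates 1 and 2. In KO replicate 3 these genes stood at a median log2 of 2.81 above the other KO libraries and the granulocyte and monocyte genes at 2.64. S100a8, a neutrophil protein, was at 31873, 12024 and 2096 in fl/fl replicates 1 to 3 and at 21757, 12316 and 153117 in KO replicates 1 to 3. The granulocyte and monocyte list had no limma call among 19 genes (camera, adjusted p = 0.577), with pair medians of -1.17, -0.450 and 2.31. Without both libraries numbered 3 camera with the preset correlation called it lower (adjusted p = 0.00143). The lists of B cell (8 genes, camera adjusted p = 0.567), mast cell and basophil (8, 0.927), endothelial and stromal (10, 0.840) and multipotent progenitor markers (9, 0.927) had no call either. For these 5 lists the count adjusted over the list alone was 0 in both directions, with 2, 0, 1, 1 and 3 genes at an unadjusted p below 0.05, and edgeR and DESeq2 called 0 apart from 1 multipotent progenitor gene by DESeq2. In the B cell list 7 of 8 folds were below 0 (median log2 -0.572), with pair medians of -0.376, -0.546 and -0.252. The multipotent progenitor median was -0.0991 while camera's direction was up, and the endothelial and stromal list gave 0.146.

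Lists of the cell cycle, protein synthesis and metabolism held no gene past the limma threshold. Nuclear-encoded subunits of oxidative phosphorylation (78 genes, median log2 0.08) were higher by camera (adjusted p = 0.0173; with an estimated correlation adjusted p = 0.978), with pair medians of 0.334, 0.289 and -0.384. That call was lost without fl/fl replicate 1 (0.443), fl/fl replicate 2 (0.881) or KO replicate 1 (camera adjusted p = 0.373). It was 1.61e-16 without fl/fl replicate 3, with a median of 0.237, 0.0276 without KO replicate 2 and 3.82e-05 without KO replicate 3. Components of PI3K, AKT and mTOR signaling (31 genes, median 0.15) had a camera adjusted p of 0.0328, with 0.978 as the adjusted p with an estimated correlation and pair medians of -0.0771, 0.0146 and 0.634. Without fl/fl replicate 3 it was 0.647 and the median turned to -0.0389, without KO replicate 2 it was 0.0649 and without KO replicate 3 it was 0.0662. Cytosolic tRNA synthetases (20 genes, median 0.11) had a camera adjusted p of 0.0328, with 0.978 as the adjusted p with an estimated correlation. It was 0.168 without fl/fl replicate 2, 0.212 without KO replicate 1 and 0.0649 without KO replicate 2, and the median was 0.0447 without fl/fl replicate 3 (camera adjusted p = 0.0227). In these 3 lists 0 genes passed when adjusted over the list alone, 2, 2 and 0 had an unadjusted p below 0.05, edgeR called 0, and DESeq2 called 2 oxidative phosphorylation genes and 0 of the others.

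Cytosolic ribosomal proteins (78 genes, median log2 0.022; camera adjusted p = 0.0779), translation factors (41, 0.033; 0.0779) and proteasome subunits (38, 0.074; 0.218) were not called with all 6 libraries. Without Prmt5 fl/fl replicate 3 all 3 lists were higher (camera, adjusted p = 1.85e-13, 1.24e-04 and 3.49e-06), and with an estimated correlation the adjusted p was 0.907 for each. Without KO replicate 3 they were higher too (camera, adjusted p = 3.40e-05, 0.0013 and 0.015), and with an estimated correlation the adjusted p was 0.874, 0.874 and 0.928. Endoplasmic reticulum chaperones and unfolded protein response genes (22, median -0.18) had a camera adjusted p of 0.0779, and 0.00858 without fl/fl replicate 3 (with an estimated correlation adjusted p = 0.907). Adjusted over the list alone 1 of them was lower, Sdf2l1, at 3960 ± 238 and 2087 ± 343 (log2 -0.94; limma adjusted p = 0.0570). Interferon-stimulated genes (33, median -0.21) had a camera adjusted p of 0.155, and 0.0312 without KO replicate 1 (with an estimated correlation adjusted p = 0.996). Genes of the integrated stress response (22; 0.927), of G1/S and DNA replication (35; 0.840), of G2/M (29; 0.927) and of the BCL2 family and caspases (17; camera adjusted p = 0.872) were not called. Apart from Sdf2l1, the count adjusted over the list alone was 0 in all 9 of these lists. At an unadjusted p below 0.05 they held 2, 2, 1, 5, 5, 8, 0, 1 and 4 genes in the order given, edgeR called 0, and DESeq2 called 2, 0, 1, 1, 1, 2, 0, 0 and 1. Camera's direction was up for the stress response (median -0.012, mean 0.12), for G2/M (median -0.028, mean -0.047) and for the BCL2 family (median -0.143, mean -0.034), and the G1/S mean of -0.018 lay below 0 while its median was 0.029.

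Prmt5 fl/fl replicate 3 stood apart from the other libraries in its content of long genes. Its reads came from genes of a mean length of 2.87 kb, against 3.37 and 3.41 kb in the other fl/fl libraries and 3.25, 3.34 and 3.32 kb in the KO libraries. Across genes, its ratio to the other fl/fl libraries fell with gene length (Spearman -0.574 over genes, which are not independent replicates), from a median log2 of 0.457 in the shortest length class to -0.695 in the longest. The log2 fold change between genotypes had a Spearman correlation with gene length of 0.242 with all libraries and of -0.0591 without that one. The ribosomal, oxidative phosphorylation and proteasome lists went up in the first and second pairs and down in the pair that holds it.

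**Figure D4:**
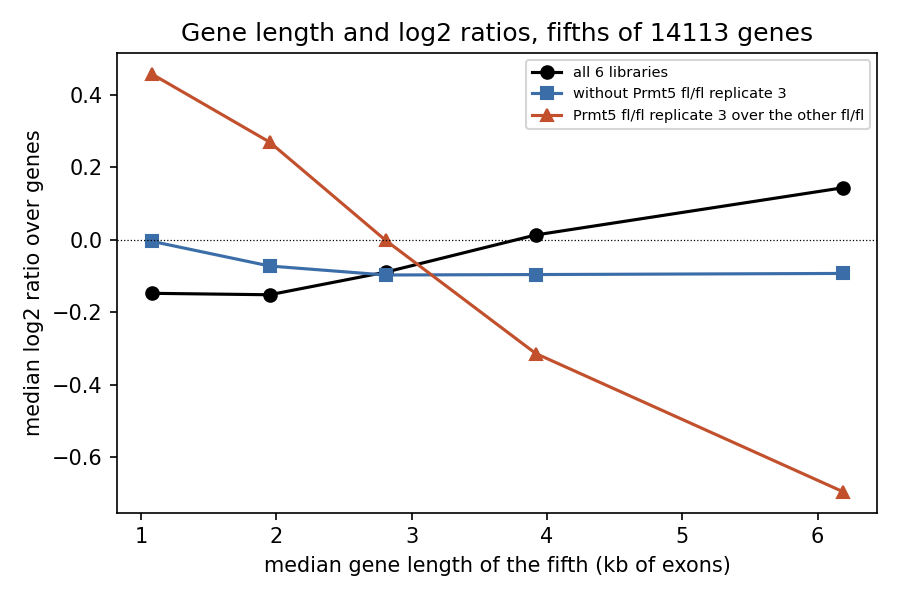
Median log2 ratio over genes in 5 classes of gene length (vertical axis) against the median gene length of each class in kb (horizontal axis), with 1 line for Prmt5 KO over fl/fl with all 6 libraries, 1 without fl/fl replicate 3, and 1 for fl/fl replicate 3 over the other fl/fl libraries. The last line runs from 0.457 to -0.695, the first from -0.148 to 0.143, and the line without that library from -0.0045 to -0.0932.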

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

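The fits with the length trend removed and without both libraries numbered 3 were chosen after seeing the data. So were those with an estimated correlation and 1 library left out. The length trend removed was a joint one on gene length and mean expression. All 103 called genes kept their direction in every fit that tested them. So did the 25 named genes past the threshold in 20 alternatives and 40 of the 48 not past it, but the number past the threshold moved. With the groups of all 103 apart, fits on the main scaling, among them the block and the leave-outs, could not turn the direction of these genes. Fits that rescale the values could have. Against 39 higher and 64 lower, limma called 1 and 0 with the replicate block (1981 genes at an unadjusted p below 0.05), 495 and 1169 with robust estimates and array weights, 128 and 166 with the length trend removed, 237 and 419 without both libraries numbered 3, and 115 and 401 at an adjusted p below 0.1. DESeq2 called 365 and 616 (299 genes without an adjusted p). The lower genes numbered 38 with no filter, which tests 17876 genes, 22 with median-of-ratios size factors, 26 with quantile normalization and 26 with edgeR. Leaving out 1 library gave 1 to 121 higher and 2 to 257 lower genes. Of the 103, 66 stayed past the threshold with no filter, 57 with median-of-ratios, 58 with quantile normalization, 60 with edgeR, 62 with limma without the trend, 96 with the length trend removed and 103 with array weights, with DESeq2 and without fl/fl replicate 3. Pseudocounts, the stricter filter, limma without the trend and a fold limit of 2 kept both counts within 1.5 times. The common total counts among the 20 alternatives but was bound to repeat the main fit, since the deposited values already share 1 total. Why the counts moved was not tested. Fewer libraries did not always mean fewer calls, since limma called 121 higher and 257 lower without fl/fl replicate 3.

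The block left Prmt5 at a log2 of -2.60 (limma, adjusted p = 0.0618), ended 23 other named calls and the call of the Sm and LSm list, and changed no other list. The 9 lists called by camera became 0 with an estimated correlation, 0 with fry, and 5 to 13 without 1 library. With both an estimated correlation and 1 library left out camera called 0 lists, except that it called 1, the p53 targets, without KO replicate 2 (adjusted p = 0.0452; without fl/fl replicates 1 to 3 it was 0.971, 0.978 and 0.907, and without KO replicates 1 and 3 it was 0.685 and 0.548). The p53 target genes had an adjusted p of 0.770 with camera's estimated correlation and 0.0878 with fry, and kept their call in the 20 alternatives with the preset correlation (9.1e-36 to 0.978 over all). The granulocyte and monocyte markers turned to a lower call without both libraries numbered 3 (camera with the preset correlation, adjusted p = 0.00143). This list's range over the alternatives was 0.00143 to 0.996. With an estimated correlation its camera adjusted p was 0.978 with all libraries, and that test was not run without both libraries numbered 3. Over their alternatives the camera or fry adjusted p ran from 2.19e-04 to 0.996 for erythroid, 8.73e-08 to 0.978 for megakaryocyte and platelet markers, and 1.76e-10 to 0.996 for the SR and hnRNP list.

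The 8 named genes whose direction turned were not called in the fits that turned them. With array weights Kit was -0.2955 and Carm1 -0.05829. With the length trend removed Kit was -0.06646, Cd48 0.1624 and Wdr77 -0.03802. Without both libraries numbered 3 Kit was -0.3571, Slamf1 0.0047, Carm1 -0.05205 and Prmt7 0.01679, and with quantile normalization Wdr77 was -0.01157. Without 1 library the log2 fold ran from -0.3616 to 0.4121 for Kit, -0.3018 to 0.0793 for Cd48, -0.0947 to 0.3231 for Carm1, -0.0467 to 0.0964 for Wdr77, -0.0574 to 0.0407 for Riok1 and -0.0404 to 0.2603 for Coprs. With 37834096 to 44704636 counts per library, depth did not set the spread of a low gene such as Slc4a1 (0 to 110 in KO): its reads differed between libraries by a chi-square per degree of freedom of 888 in fl/fl and 93.9 in KO, where counting error alone gives about 1.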

Other observations

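The tests of other splits, of the label and of other cell types in Prmt5 fl/fl replicate 3, of intron length over all genes, of erythroid cells in differing amounts and of the length shift on the marker lists were chosen only after the result was seen. Several genes past the threshold were singled out after their values were seen. Epha2, an ephrin receptor, rose from 32.7 ± 3.54 to 601 ± 173 scaled counts (SD, n = 3 each; log2 4.12), Spry4, a feedback inhibitor of ERK signaling, from 50.1 ± 17.2 to 313 ± 74.9 (log2 2.65), and Ccnd1, cyclin D1, from 875 ± 81.4 to 2093 ± 270 (log2 1.25). The limma adjusted p was 0.00564, 0.0304 and 0.0304. Chga, the granule protein chromogranin A, rose from 7.81 ± 3.77 to 304 ± 109 (log2 5.14; limma adjusted p = 0.0122). Prpf3, a protein of the U4/U6 snRNP, rose by a log2 of 0.72 (limma, adjusted p = 0.0431) and Smndc1, a splicing factor related to SMN, by 0.91 (0.0428). Zranb2, a splicing regulator, went from 6114 ± 139 to 3237 ± 311 (log2 -0.92; limma adjusted p = 0.0371). The erythroid adhesion molecule Icam4 (log2 -2.45), the Rh-associated glycoprotein Rhag (log2 -1.97) and the heme pathway enzyme Blvrb (log2 -1.72) fell, with limma adjusted p of 0.0195, 0.0195 and 0.0476. With the replicate block the limma adjusted p was 0.103 for Epha2, 0.161 for Chga, Icam4 and Rhag, and 0.197 for the other 6 of these genes. Without KO replicate 1 or KO replicate 3 limma called Gem, Prmt5 and Mfsd2b alone, so the calls of all these genes were lost.

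It was hypothesized that the output of ERK signaling is higher in Prmt5 KO cells. Among 22 tested feedback and immediate early genes, 4 were called (Epha2, Spry4, Ccnd1 and Egr1) and 7 had been seen when the list was written. Of the 15 members that had not been seen, 13 had a fold above 0 with a median log2 of 0.482, and camera's set test across genes gave 0.000689, or 0.095 with an estimated correlation and 0.00181 without fl/fl replicate 3. Dusp5, an ERK phosphatase, had the smallest limma adjusted p among them (0.0641, log2 1.24), while Myc and Spry1 were at -0.29 and -0.25. Some of the higher members spread widely in KO, with Fos at 2908 ± 2860, Fosl1 at 145 ± 162 and Phlda1 at 410 ± 416 (SD, n = 3). Others did not, with Dusp4 at 1163 ± 134 and Dusp5 at 837 ± 227. This list was not tested without a KO library or with the replicate block, so a single KO library may carry part of the result. The hypothesis may hold, but it rests on the preset correlation, and phosphorylated ERK was not analysed here. It was also hypothesized that genes carrying blood group antigens are lower as a class, since Rhag, Art4, Icam4 and Ache were among the lower genes. The 22 members not seen before had a median log2 of -0.0763 and a camera value of 0.784. Under the bounds set in advance these values counted against the class. They leave out the 4 called genes, so they speak only for the members not seen before, with 10 folds above 0 and 12 below. Those members included Smim1 (log2 -1.68, limma adjusted p = 0.080), Slc14a1 (log2 -0.90, 0.0587) and Bcam (log2 0.78, 0.0866).

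Other splits of the 6 libraries were compared with the real one. Of 10 splits into 3 against 3, 1, the real one, gave as many as 103 genes, and the highest of the others gave 0. The splits are too few for a share under 0.05. Of the 4 splits that part all 3 same-number pairs, the real one gave 103 genes and the others 0.

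Prmt5 fl/fl replicate 3 lay at -79.3 on the first principal component (42.6% of the variance), against -4.00 and -21.2 for the other fl/fl libraries, and its distance from them was weighed. Prmt5 KO replicate 3 lay apart on the other side, at 60.6 against 29.0 and 14.9 for the other KO libraries, and differed from them by a chi-square per degree of freedom of 119 and 137, against 26.2 between those. Its median log2 ratio over them was 2.81 for T and natural killer cell markers and 2.64 for granulocyte and monocyte markers. It was 0.921 for red cell precursors, 0.897 for mast cells, 0.842 for B cells and lowest, at -0.115, for megakaryocytes and platelets. The test of other cell types was not run for that KO library. For fl/fl replicate 3, a Prmt5 KO library under a wrong label is argued against, since its Prmt5 value of 6010 lay beside 6076 and 6024 and above every KO library. A loss of reads from long genes, as partly degraded RNA or a different amplification may give, stays open. Taking off a trend on gene length alone closed 40.4% of the gap in correlation (from 0.0219 to 0.013), between the bounds set in advance. Other cell types, and an untested biological difference between these mice, stay open too, with the highest marker list, that of megakaryocytes and platelets, at a median log2 ratio of 0.582, and lower ones for mast cells (-1.49), granulocytes and monocytes (-1.35) and red cell precursors (-0.885); the bound against other cell types was lowered from 1 to 0.5 after the highest value was seen, and under the first wording it would have counted against them.

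Genes that fell in Prmt5 KO had short introns: of the 64 fallen genes, 56 (87.5%) had values, and the 49 that are protein-coding with more than 2 exons had a median intron of 778 bp, against 1490 bp over all genes. Sets matched on gene length and expression had a median of 1627 bp (95% range 1186 to 2114), and a share of 1e-04 of 10000 sets, the smallest they can give, was as short; with GC content matched too, the median was 1352 bp (990 to 1801) and the share 0.0016, so neither length and expression nor GC content is likely to account for it. The 31 higher genes with such values had a median intron of 1320 bp, against 1590 bp in sets matched on length and expression (share 0.16) and 1728 bp with GC content matched too (share 0.045), so shorter introns were not shown to be particular to the fallen genes. A loss of short-intron genes as a class is argued against: over 11765 genes the partial Spearman correlation of log2 fold with intron length was -0.041, -0.019 without fl/fl replicate 3 and -0.032 with the length trend removed. Retained introns in the fallen genes are a candidate explanation that was not tested here, since the deposited values hold no intron reads.

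The lower erythroid and megakaryocyte markers were weighed against the make-up of the sorted cells, although the gate, Lineage-negative and Sca-1-positive, is meant to remove committed cells of both kinds. For the erythroid list, more committed cells in the fl/fl libraries in differing amounts may account for the drop. The median log2 range between the fl/fl libraries was 2.61, above the fold of 2.10 between genotypes, and 1.72 between the KO libraries. The list's median log2 value was 10.8, 8.44 and 8.62 in fl/fl replicates 1 to 3 and 7.11, 6.22 and 7.54 in KO replicates 1 to 3. Replicate 1 thus stood highest in fl/fl, and no KO library reached a fl/fl one. The Klf1 values of the genotypes did not overlap either. A wide range alone cannot tell such cells from lower transcript levels within the stem cells. For the megakaryocyte list, more megakaryocytes or platelets in the fl/fl libraries stay open. Pf4 (-0.63 ± 0.41, SE) and Ppbp (0.77 ± 0.86) averaged a log2 fold of 0.0704, above the bound of -0.5 set in advance. Under that bound the values counted against this explanation. Pf4 and Ppbp went opposite ways, however, Pf4 as far as the list's median of -0.63. On that ground the bound was taken to decide nothing, a rule written after the values were seen. The length shift of fl/fl replicate 3 is argued against for both lists, whose median log2 folds without that library were -2.31 and -0.69. With the preset correlation their larger camera adjusted p, without that library or with the joint length and expression trend removed, was 0.00413 and 3.6e-04. With an estimated correlation neither list was called with all libraries (camera adjusted p = 0.949 each) or without that library (0.907 each). A lower megakaryocyte and erythroid program within the stem cells of Prmt5 KO mice stays open, as a hypothesis.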
